A study of Mus musculus with 24 samples.

How the data were processed

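Biotin-labelled cRNA from primary cortical neurons of mouse fetuses was hybridized to 24 Illumina MouseRef-8 V1.1 bead arrays, which lay on 3 slides with 8 arrays each: 2 controls and 1 array of each treated group per slide. Every treated group kept 1 position on the slides, so position and group cannot be told apart. Per the file headers the scanner table was made in BeadStudio 3.2.6 without normalization and gives the mean bead signal of each gene as an intensity in arbitrary units, together with a detection score between 0 and 1 as a fraction. The deposited non-normalized table gives the signal of 24691 probes as intensity, of which 24613 have values (minimum 24.5). The background step that led to these signals is not given in the sources used here. The authors' normalized table holds a ratio on a linear scale, recomputed here as the signal divided by the array median and then by the mean of the controls (largest difference 1.87e-05), and the series matrix holds 24393 probes with the same ratio. The authors' ratio table served only as an alternative. Values of log2 intensity were computed here from the deposited signals, and log2 changes from those.

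The array labels were checked against the scanner table. Under each treated label the deposited values match a scanner column of the same group on another slide (within 1e-06 for 99.9% of the 14487 genes compared), with replicate 1, 2 and 3 holding the arrays labelled 3, 1 and 2, while the controls match their own labels. Groups are unaffected, replicates are named here by the labels of the deposited table, and slides are those of the matching scanner column. The detection score was carried to each probe from genes with a single probe on the same array.

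All steps were run in R 4.3.3 with limma 3.58.1. Background was corrected with nec (normexp with negative controls inferred from detection p, offset 16), followed by quantile normalization and log2. Probes detected at the 0.01 level on at least 3 arrays were kept (13539). The brightest probe of each gene on average was tested: 10878 genes, of which 2082 had several kept probes. Probes were matched by RefSeq accession to current mouse symbols (GRCm38.p6, 20514 probes, of which 7145 changed symbol); 225 probes with values and 49 of the kept ones had no symbol. A second probe of Gstm1 had the opposite sign at 5 h (0.24 against -0.96) and at 24 h of 1 µM (0.070 against -1.93) without passing the test.

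A linear model with 7 group means and no block was fitted with limma (17 residual degrees of freedom, moderated by eBayes with 4.29 prior degrees of freedom), and 11 contrasts were tested: each treated group against the 6 controls, the doses against each other at 15 and 24 h, 24 h against 5 h at 1 µM, 24 h against 15 h at 0.1 µM, and the dose by time interaction. A gene was called at Benjamini-Hochberg adjusted p < 0.05 within its contrast. Gene lists (31, written from general knowledge) were tested with camera at a correlation of 0.01 between genes, adjusted over the 31 lists, and again with the correlation estimated for each list. Some genes are on several lists, such as Bbc3 and Pmaip1 (p53 targets and proapoptotic genes) and Slc7a11 (ATF4 and NRF2 targets). Lists that share genes are not independent. Genes named are the 5 largest rises and 5 largest falls among called genes with the same direction on all 3 slides that were detected on every array of the brighter group, up to 4 members of each list, and 25 genes fixed in advance. Of those 25, Hspa1a, Hspa1b and Psmd1 have no probe, Nefl was not detected, and Snap25 and Bdnf were detected on 4 and 5 arrays and are not described. Some further genes that the rule selects are not reported here. The sample sheet, the comparisons, the lists, the naming rule and most alternatives were fixed before the data were examined.

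The alternatives tried were no background correction, offset 50, median centring, cyclic loess, no filter or a stricter filter on dim probes, all kept probes, a fit of only the groups compared, slide as a block, array weights, a variance trend with robust estimation, the authors' ratio table, and the fit without each array in turn. Added after the data were seen were the slide given by the labels as a block, the fit without controls 5 and 6, and a separate variance for control arrays. The pipeline was tested on simulated data with changes of 1.5, 2 and 4-fold set in 67, 67 and 66 of 10878 genes. For 5 h at 1 µM 70.1%, 95.5% and 100% of them were recovered, and for 24 h at 0.1 µM 73.1%, 98.5% and 100%. For 24 h at both doses compared 59.7%, 86.6% and 100% were recovered. False calls numbered 14, 7 and 9. The simulated noise was independent between arrays and had the same variance on all of them. It held neither the correlation within slides nor the wider spread of the controls, so these rates do not carry over to the comparisons with controls.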

Results

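Gene expression was measured with 24 Illumina MouseRef-8 bead arrays, 1 per RNA sample, from primary cortical neurons of fetal mice on day 5 in culture. Lactacystin blocks the proteasome, the complex that degrades ubiquitin-tagged proteins. It was given at 1 µM for 5, 8, 15 or 24 h and at 0.1 µM for 15 or 24 h, with 3 arrays in each of these 6 groups. A further 6 arrays came from untreated cultures. The question addressed is which genes rise and fall in the RNA of these cultures at a high and a low concentration of the inhibitor, and when. Glial markers such as the oligodendrocyte lineage gene Sox10 were also expressed in the controls. The changes can therefore not be assigned to neurons alone. The labels give neither a collection time nor a vehicle for the controls, so time in culture and solvent are part of every comparison with them. Median signal per array lay between 52.2 and 81 intensity units (62.6 ± 6.27, mean ± SD, n = 24), and 11275 to 12208 probes per array were detected (11778 ± 300). After filtering, 10878 genes were tested. Arrays of the same treated group differed by a root mean square of 0.209 to 0.31 log2 units (18 pairs) and control arrays by 0.287 to 0.544 (15 pairs). Changes below are log2 differences ± SE from limma (3 treated against 6 control arrays, or 3 against 3) with Benjamini-Hochberg adjusted p. Each SE rests on a variance shared by all 24 arrays, so it is not the spread of the arrays compared alone. Fits of only the groups compared called fewer genes against the controls (131 for 1119 at 5 h of 1 µM). Between the doses they called more (5960 for 5595 at 15 h). Nothing in the labels says that the arrays of a group came from separate cultures, so the p-values measure only the spread between these samples. The number of arrays limits the precision. Where 1 side of a comparison was detected on no array, the change is given as at least N-fold, counted from the detection level. Among the 6 controls Trib3, Nupr1, Phlda3, Bbc3, Nol3, Grp and Sirpa were detected on 5 arrays, Hspb1, Osgin1 and Pmaip1 on 3, Cxcl1 on 2 and Atf3 on 1.

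After 5 h at 1 µM, genes of early stress signalling rose. The largest rise was in Trib3, a pseudokinase induced by the transcription factor ATF4 (2.41 ± 0.36, adjusted p = 1.83e-04). The AP-1 subunit Fos (2.35 ± 0.50, adjusted p = 0.0045) and Ier3 (2.33 ± 0.12, adjusted p = 1.10e-10) rose. So did the NRF2 target Osgin1 (2.24 ± 0.17, adjusted p = 2.53e-08) and the AP-1 subunit Fosb (2.16 ± 0.42, adjusted p = 0.00199, detected on 1 of 6 control arrays). Control 5 alone lay above the 5 h mean in Fos (log2 intensity 9.702 against 9.563) and Fosb (7.186 against 7.052). In Trib3 controls 5 and 6 (7.345 and 7.291) lay between the other controls (4.976 to 6.248) and the 5 h mean (8.594). The largest falls were in Tmem100 (-1.48 ± 0.12), the matrix protein gene Prelp (-1.44 ± 0.21), the lipogenic regulator Thrsp (-1.15 ± 0.27), Dclk3 (-1.07 ± 0.25) and Bdh2 (-1.06 ± 0.24). Of 29 measured ATF4 targets, which handle amino acid supply and stress, 15 rose (19 adjusted over the list alone), among them Atf3 (1.92 ± 0.14), Chac1 (1.92 ± 0.29) and Ddit3 (1.77 ± 0.18). Their median was 0.50 (camera adjusted p = 1.49e-15, adjusted p = 0.062 with an estimated correlation). Of 23 immediate early genes 14 rose (16 adjusted over the list alone; median 0.71, camera adjusted p = 2.96e-14). Proteasome subunits rose early too: 13 of 32 (17 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 2.38e-09). Among them were Psmc5 (0.56 ± 0.075) and Psmd4 (0.55 ± 0.086). Of 25 genes on the list of p53 targets 6 rose (7 adjusted over the list alone), led by Gadd45g (0.97 ± 0.099) and Gadd45a (0.81 ± 0.10). The list median was 0.13 (camera adjusted p = 0.00718), and p53 activity was not measured. The NRF2 oxidative stress genes had no common direction: 5 of 27 rose and 2 fell (6 and 4 adjusted over the list alone). The median of -0.010 and the mean of 0.096 differed in sign (camera adjusted p = 0.586). Within the 3 slides the list medians were 0.48, 0.98 and 0.22 for ATF4 targets, and 0.77, 0.82 and 0.42 for immediate early genes. They were 0.33, 0.26 and 0.24 for proteasome subunits and 0.21, 0.19 and 0.12 for p53 targets.

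At 5 h limma called 674 genes higher and 445 lower (57 and 7 of them by at least 2-fold), with 97.4% in the same direction on all 3 slides. Genes were called on these same slides, so such agreement is largely built in, here and below. The median absolute change of the called genes was 0.541, 0.564 and 0.305 on slides 1, 2 and 3. The balance of higher and lower calls turned with the scaling: 283 higher and 390 lower with each array centred on its median, and 410 and 543 in the authors' normalized table. The total of 1119 also moved to 131 in a fit of the 9 arrays compared, to 2395 with array weights, to 563 and 453 without 5 h replicate 2 and replicate 3, to 1683 without control 5 and to 2549 without controls 5 and 6. In the fit of the 9 arrays Fos (adjusted p = 0.125), Fosb (0.0867), Thrsp (0.151), Dclk3 (0.158) and Bdh2 (0.139) did not pass, and without 5 h replicate 3 neither did Dclk3 (0.064) or Bdh2 (0.0672).

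At 8 h of 1 µM ATF4, proteasome and heat shock genes were higher than in the controls, and synaptic vesicle and respiratory chain genes lower. Trib3 rose by 3.69 ± 0.36 (adjusted p = 6.86e-08), Atf3 by 3.61 ± 0.14 (adjusted p = 7.69e-14), the stress-induced Nupr1 by 3.03 ± 0.17 and Tnfrsf12a, the receptor of the cytokine TWEAK, by 2.95 ± 0.15. The secreted stress factor Gdf15 rose at least 6.89-fold (adjusted p = 7.69e-14), and it was detected on no control array. Prelp fell by 2.91 ± 0.21 (adjusted p = 7.44e-10), Thrsp by 2.34 ± 0.27 (detected on 1 of 3 treated arrays), 0610041G09Rik by 2.23 ± 0.36, the astrocyte water channel gene Aqp4 by 2.03 ± 0.24 and the claudin gene Cldn10 by 1.94 ± 0.17. Of 29 ATF4 targets 26 rose (also 26 adjusted over the list alone; median 1.14, camera adjusted p = 2.26e-16). Of the proteasome genes 24 of 32 were higher and 1 lower (27 and 1 adjusted over the list alone; median 0.66, camera adjusted p = 3.77e-11). Psmd4 rose by 1.29 ± 0.086 and Psmc2 by 1.32 ± 0.30, and only Psmd10 fell (-0.59 ± 0.089). Of 25 heat shock genes 14 rose and 2 fell (14 and 2 adjusted over the list alone; median 0.44, camera adjusted p = 7.66e-06). The small chaperone genes Hspb1 (2.31 ± 0.16, detected on 3 of 6 control arrays) and Hspb8 (2.17 ± 0.23) stood against Cryab (-1.41 ± 0.27), and the metallothionein gene Mt1 fell by 1.33 ± 0.12. Of 25 synaptic vesicle and release genes 16 fell (18 lower and 1 higher adjusted over the list alone; median -0.32, camera adjusted p = 1.35e-04). Among them was the vesicular glutamate transporter gene Slc17a7 (-0.81 ± 0.20). Of 41 respiratory chain genes 26 fell (27 adjusted over the list alone), led by Cox7a2 (-1.17 ± 0.21; median -0.29, camera adjusted p = 1.47e-07). Of 19 cholesterol synthesis genes 13 fell, Nsdhl by 1.08 ± 0.11 and Mvd by 1.02 ± 0.22 (also 13 adjusted over the list alone). Their median was -0.45 (camera adjusted p = 2.40e-04, adjusted p = 0.259 with an estimated correlation). Within the slides the medians were 1.32, 1.52 and 0.86 for ATF4 targets, and 0.82, 0.75 and 0.50 for proteasome subunits. They were 0.49, 0.45 and 0.37 for heat shock genes and -0.38, -0.30 and -0.29 for synaptic vesicle genes. limma called 2186 genes higher and 2161 lower, 194 and 122 by at least 2-fold, with 97.9% in the same direction on every slide. Centring each array on its median gave 2262 and 1437.

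At 15 h the largest change was the induction of a small heat shock gene. Hspb1 rose by 6.93 ± 0.16 (adjusted p = 1.28e-18), Tnfrsf12a by 5.26 ± 0.15 (adjusted p = 8.38e-17), Atf3 by 4.59 ± 0.14 and Trib3 by 4.32 ± 0.36, and Gdf15 rose at least 24.3-fold. On the falling side stood genes of glia and their precursors. These were the oligodendrocyte lineage regulator Sox10 (-4.42 ± 0.086, adjusted p = 9.23e-20, detected on 2 of 3 treated arrays), the precursor receptor gene Pdgfra (-4.06 ± 0.12, adjusted p = 1.36e-16) and the Notch target Hes5 (-3.99 ± 0.14, detected on 2 of 3). Prelp (-3.24 ± 0.21, detected on 1 of 3) and the myelin-associated Bcas1 (at least 11.2-fold lower) fell too. Of 25 heat shock genes 18 rose and Hspa2 (-1.13 ± 0.12) and Fkbp4 (-0.28 ± 0.085) fell (19 and 2 adjusted over the list alone; median 1.45, camera adjusted p = 7.94e-09). Most proteasome genes were higher, 27 of 32, and Psmd10 was lower (-0.90 ± 0.089; also 27 and 1 adjusted over the list alone; median 0.92, camera adjusted p = 6.06e-10). Psmc2 rose by 1.66 ± 0.30 and Psmd4 by 1.43 ± 0.086. Of 29 ATF4 targets 27 rose (28 adjusted over the list alone; median 1.38, camera adjusted p = 2.87e-14). Of 25 p53 targets, which arrest the cell cycle or promote death, 20 rose and 2 fell (20 and 2 adjusted over the list alone; median 1.09, camera adjusted p = 1.74e-08). Gadd45a rose by 3.39 ± 0.10, Phlda3 by 2.47 ± 0.20, Cdkn1a by 1.77 ± 0.11 and Bbc3 by 1.46 ± 0.16. Of 27 NRF2 targets 15 rose and 4 fell (16 and 4 adjusted over the list alone; median 0.35, camera adjusted p = 0.00198, adjusted p = 0.309 with an estimated correlation). Hmox1 (3.59 ± 0.21) and Srxn1 (3.17 ± 0.21) stood against Gstm1 (-2.08 ± 0.13) and G6pdx (-1.07 ± 0.13). Only 12 of the 23 listed inflammatory genes were measured, without Il1b, Il6 or Tnf. Of the 12, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.99 (camera adjusted p = 0.00198). Cxcl1 rose by 3.11 ± 0.15 and Csf1 by 1.80 ± 0.19.

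Neuronal and glial lists fell at 15 h. Of 25 synaptic vesicle genes 18 fell, Rph3a at least 2.44-fold, and Slc17a6 rose (0.43 ± 0.10; also 18 and 1 adjusted over the list alone; median -0.57, camera adjusted p = 1.38e-05). Of 13 genes of GABAergic interneurons 10 fell and 1 rose (10 and 1 adjusted over the list alone; median -0.98, camera adjusted p = 9.04e-04). The calcium-binding Calb2 was at -2.79 ± 0.14, Cck at -1.66 ± 0.17 and the GABA-synthesizing Gad1 at -0.69 ± 0.14 (adjusted p = 2.81e-04). Of 15 astrocyte markers 11 fell and Vim rose (0.77 ± 0.13; 11 and 2 adjusted over the list alone; median -0.94, camera adjusted p = 0.00198, adjusted p = 0.196 with an estimated correlation). Aqp4 fell by 2.88 ± 0.24 and Aldoc by 2.42 ± 0.11. Of 11 oligodendrocyte markers 8 fell (also 8 adjusted over the list alone; median -0.76, camera adjusted p = 2.98e-05). Of 19 cholesterol synthesis genes 14 fell (also 14 adjusted over the list alone), Mvd and Nsdhl both by 2.44 (SE 0.22 and 0.11). Their median was -0.59 (camera adjusted p = 1.52e-05, adjusted p = 0.167 with an estimated correlation). Proapoptotic genes were split: of 28, 12 rose and 10 fell (12 and 11 adjusted over the list alone; median 0.11, camera adjusted p = 0.667). The BH3-only gene Bcl2l11 stood at 1.94 ± 0.16 and the inflammatory caspase gene Casp1 at 1.62 ± 0.13 against Bad at -0.89 ± 0.098 and Bok at -0.83 ± 0.09. The antiapoptotic gene Bcl2 did not pass the test (0.23 ± 0.17, adjusted p = 0.246). Within the slides the medians were 1.31, 1.25 and 1.35 for heat shock genes, 0.90, 0.92 and 0.85 for proteasome subunits and -0.57, -0.68 and -0.64 for synaptic vesicle genes. They were -1.22, -1.03 and -0.59 for astrocyte markers and -0.90, -0.60 and -0.72 for oligodendrocyte markers. limma called 2959 genes higher and 3021 lower (595 and 659 by at least 2-fold), 98% of them in the same direction on every slide. The split was 2332 and 3076 with median centring and 2467 and 3197 in the authors' table.

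**Figure D1:**
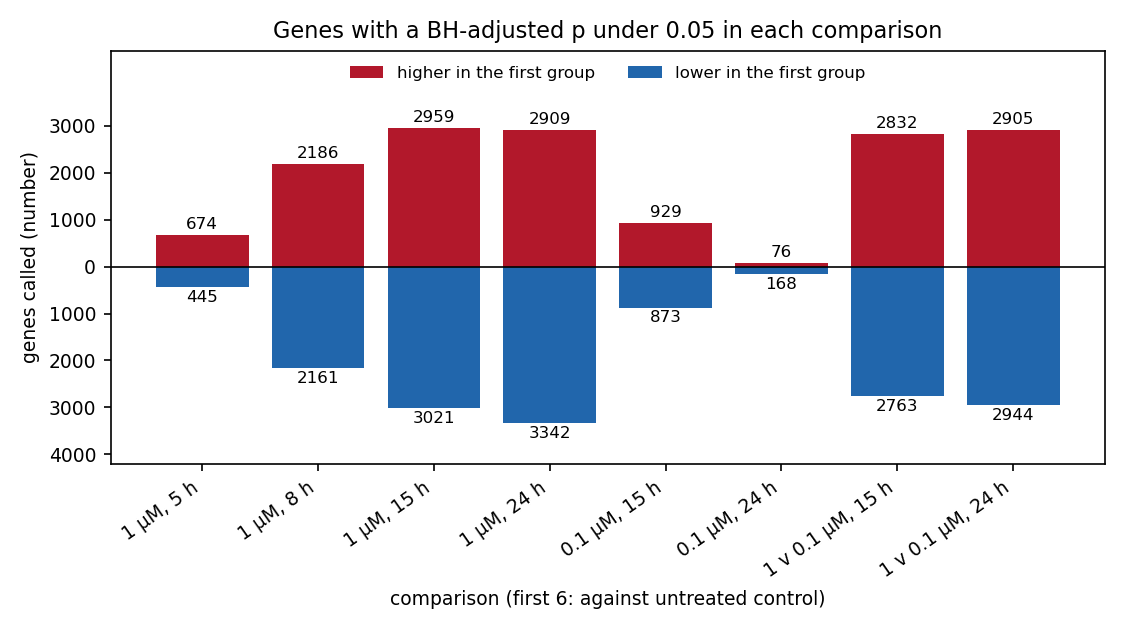
Genes called higher (up) and lower (down) by limma in each comparison with the 6 controls and between the doses, as number of genes out of 10878. At 15 and 24 h the totals were 5980 and 6251 at 1 µM and 1802 and 244 at 0.1 µM; the latter 2 were 2035 and 2204 with median centring and 2056 and 1934 in the authors' table.

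At 24 h of 1 µM heat shock, proteasome, ATF4, p53 and NRF2 genes were again higher than in the controls. The list medians of p53 and NRF2 targets were above those at 15 h, a difference that was not tested. Hspb1 rose by 7.35 ± 0.16 (adjusted p = 5.78e-19), Tnfrsf12a by 5.72 ± 0.15 (adjusted p = 1.19e-17), Hspb8 by 4.56 ± 0.23, 1110055E19Rik by 4.51 ± 0.16, and Gdf15 at least 27.9-fold. Sox10 fell by 3.92 ± 0.086 (adjusted p = 5.78e-19), Pdgfra, Aqp4 and Hes5 each by 3.58 (SE 0.12, 0.24 and 0.14) and the glycolytic astrocyte gene Aldoc by 3.55 ± 0.11. Of 25 p53 targets 21 rose and 2, Ddb2 (-0.67 ± 0.14) and Xpc (-0.44 ± 0.077), fell (21 and 2 adjusted over the list alone; median 1.40, camera adjusted p = 2.38e-09). Ccng1 rose by 2.93 ± 0.15, Cdkn1a by 2.34 ± 0.11 and Bbc3 by 1.60 ± 0.16. Of 27 NRF2 targets 21 rose and Gstm1 (-1.93 ± 0.13, another probe 0.070 and not called) and G6pdx (-0.71 ± 0.13) fell (22 and 2 adjusted over the list alone), while Hmox1 rose by 3.47 ± 0.21 and Srxn1 by 3.17 ± 0.21. The list median was 0.92 (camera adjusted p = 1.33e-06, adjusted p = 0.115 with an estimated correlation). Of 25 heat shock genes 19 rose and 3 fell (also 19 and 3 adjusted over the list alone; median 1.31, camera adjusted p = 7.92e-09). The cochaperone genes Bag3 and Dnajb1 rose by 2.57 ± 0.13 and 1.44 ± 0.068. Among proteasome genes 26 of 32 rose and Psmd10 fell (-0.35 ± 0.089; 27 and 1 adjusted over the list alone; median 0.87, camera adjusted p = 5.45e-10). Of 29 ATF4 targets 27 rose (also 27 adjusted over the list alone; median 1.38, camera adjusted p = 4.12e-13, adjusted p = 0.0603 with an estimated correlation). Of 23 immediate early genes 17 rose and Nr4a3 fell (-0.88 ± 0.17; also 17 and 1 adjusted over the list alone; median 1.33, camera adjusted p = 3.54e-06), Fos by 2.13 ± 0.50. Proapoptotic genes stayed split, 14 higher and 11 lower of 28 (also 14 and 11 adjusted over the list alone; median 0.26, camera adjusted p = 0.37). Pmaip1 stood at 2.16 ± 0.23 and Endog at -0.95 ± 0.11. Of 27 listed genes of the endoplasmic reticulum stress response 18 were measured, without Atf6 or Ern1. These gave 8 higher and 3 lower (also 8 and 3 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.15). The chaperone gene Hspa5 rose by 1.48 ± 0.13.

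Of 25 synaptic vesicle genes 21 fell at 24 h (21 lower and 1 higher adjusted over the list alone; median -0.75, camera adjusted p = 5.36e-08). Of 13 GABAergic genes 9 fell and 1 rose (10 and 1 adjusted over the list alone; median -1.0, camera adjusted p = 8.72e-04). Calb2 was at -2.99 ± 0.14, Cck at -2.45 ± 0.17 and Gad1 at -1.0 ± 0.14. Of 15 astrocyte markers 12 fell and 3 rose (also 12 and 3 adjusted over the list alone; median -1.33, camera adjusted p = 0.00192, adjusted p = 0.215 with an estimated correlation). The filament gene Gfap was at -1.59 ± 0.35 (detected on 1 of 3 treated arrays) against Vim at 1.03 ± 0.13 and the gap junction gene Gja1 at 0.66 ± 0.12. Of 11 oligodendrocyte markers 8 fell (also 8 adjusted over the list alone; median -0.40, camera adjusted p = 2.47e-04). Within the slides the medians were 1.32, 1.45 and 1.16 for p53 targets, 0.58, 0.91 and 1.01 for NRF2 targets and 1.24, 1.39 and 1.34 for heat shock genes. They were 0.86, 0.88 and 0.77 for proteasome subunits and -0.89, -0.85 and -0.74 for synaptic vesicle genes. limma called 2909 genes higher and 3342 lower (684 and 695 by at least 2-fold), 98.2% of them in the same direction on every slide. With median centring, which moved the median of all genes from -0.047 to -0.148, the split was 2034 and 3766. Tested directly against 5 h, 24 h at 1 µM gave 2401 genes higher and 2771 lower (1629 and 2904 with median centring), with the heat shock genes up by a median of 1.12 and the synaptic vesicle genes at -0.86.

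**Figure D2:**
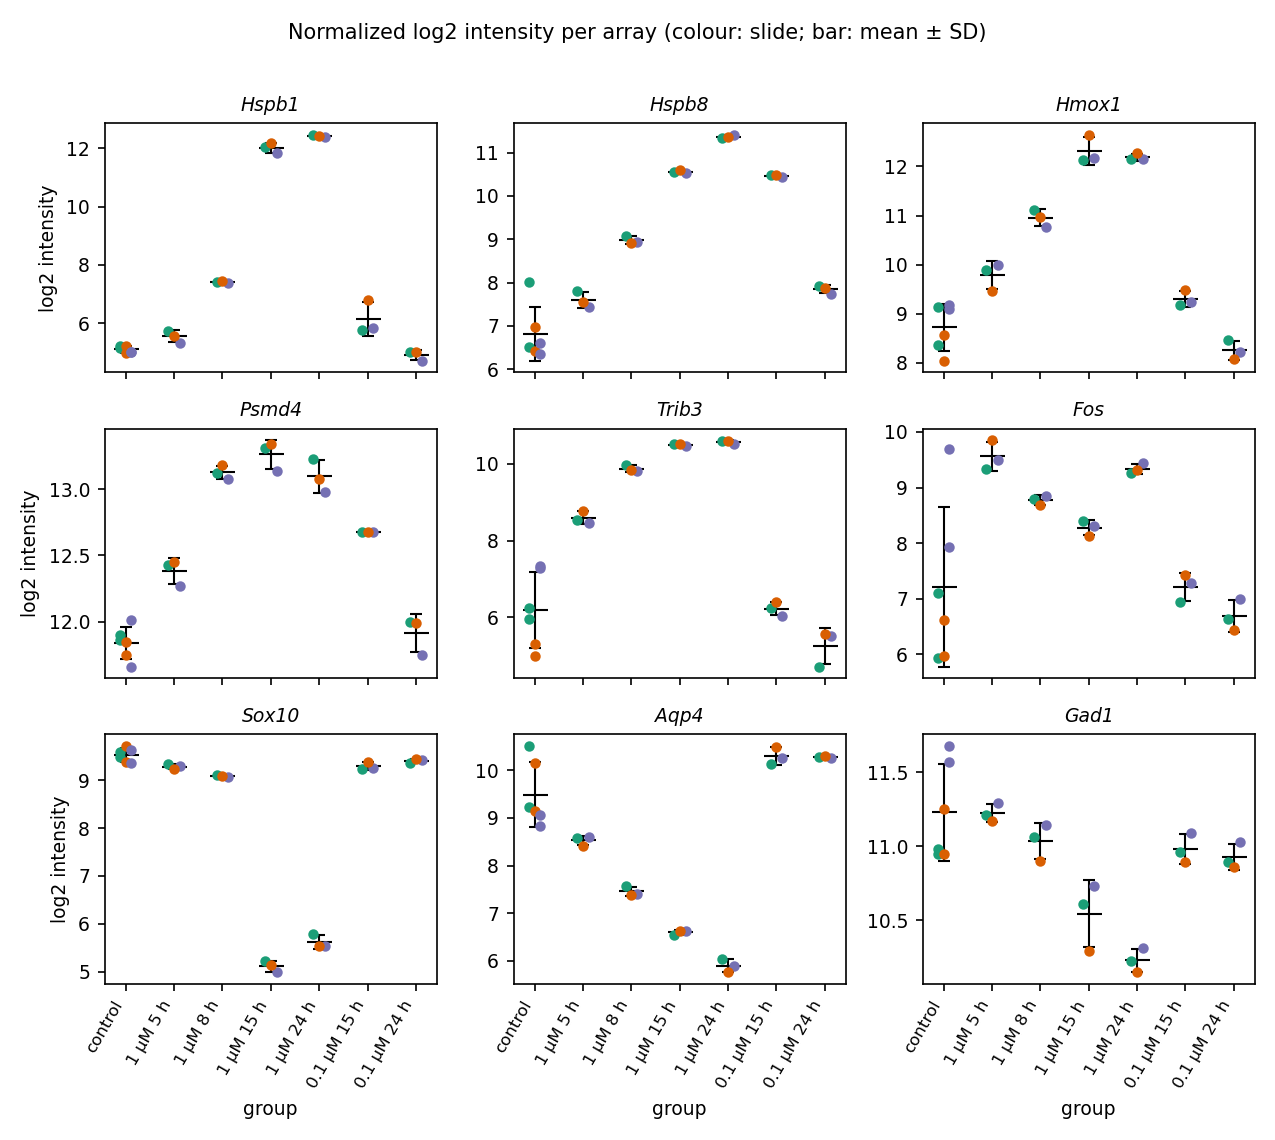
Normalized log2 intensity of 9 genes on each of the 24 arrays, by group, with the mean as a bar, ± SD, and colour for slide (n = 6 control arrays and 3 in each treated group). Hspb1 rose by 6.93 at 15 h and 7.35 at 24 h of 1 µM, and Sox10 fell by 4.42 and 3.92.

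At 0.1 µM for 15 h the proteasome and NRF2 genes rose without the ATF4 targets. The largest rises were in Hspb8 (3.66 ± 0.23, adjusted p = 1.23e-09), the apoptosis repressor gene Nol3 (2.52 ± 0.17, adjusted p = 2.76e-09) and the interferon-inducible Bst2 (2.21 ± 0.17) and Ifitm3 (2.12 ± 0.36). The secreted Ccn5 rose as much as Ifitm3 (2.12 ± 0.24, detected on 2 of 6 control arrays). The largest falls were in Pop4 (-2.23 ± 0.74, adjusted p = 0.043), the retinoic acid hydroxylase gene Cyp26b1 (-1.65 ± 0.28), neuropeptide Y (Npy, -1.44 ± 0.25), the proteoglycan gene Dcn (-1.34 ± 0.25) and 3110047P20Rik (-1.29 ± 0.13). Of the proteasome genes 23 of 32 rose (26 adjusted over the list alone), with Psma5 at 1.09 ± 0.20 and Psmb5 at 0.72 ± 0.079 (median 0.62, camera adjusted p = 1.40e-25). Of 27 NRF2 targets 22 rose (25 adjusted over the list alone; median 0.75, camera adjusted p = 6.71e-22). Blvrb rose by 1.76 ± 0.16, Srxn1 by 1.63 ± 0.21 and the autophagy receptor gene Sqstm1 by 0.88 ± 0.071. Of 25 heat shock genes 8 rose, Cryab by 1.54 ± 0.27, and 2 fell (10 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 4.13e-04). Of 29 ATF4 targets 2 rose and 4 fell (also 2 and 4 adjusted over the list alone; median -0.066, camera adjusted p = 0.343). Mthfd2 fell (-1.07 ± 0.19), and Trib3 (0.039 ± 0.36, adjusted p = 0.96) and Ddit3 (-0.17 ± 0.18, adjusted p = 0.597) did not pass the test. Of 15 astrocyte markers 6 rose, Gfap by 1.56 ± 0.35 and Vim by 0.91 ± 0.13 (also 6 adjusted over the list alone). Their median was 0.43 (camera adjusted p = 5.61e-04, adjusted p = 0.148 with an estimated correlation). Of 19 cholesterol synthesis genes 10 fell (14 adjusted over the list alone), Mvk by 1.03 ± 0.18 (median -0.42, camera adjusted p = 3.07e-06, adjusted p = 0.148 with an estimated correlation). Of 25 synaptic vesicle genes 7 fell (also 7 adjusted over the list alone), Rph3a by 0.83 ± 0.11 (median -0.14, camera adjusted p = 0.00474, adjusted p = 0.097 with an estimated correlation). Casp1 rose by 2.07 ± 0.13, while Gad1 did not pass the test (-0.25 ± 0.14, adjusted p = 0.252).

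At 0.1 µM for 15 h the list medians within the slides were 0.67, 0.70 and 0.68 for proteasome subunits, 0.55, 0.87 and 0.91 for NRF2 targets and 0.22, 0.36 and 0.62 for astrocyte markers. limma called 929 genes higher and 873 lower (135 and 18 by at least 2-fold), 99% of them in the same direction on every slide. With median centring, which moved the median of all genes from -0.027 to -0.139, the split was 541 and 1494, and it was 626 and 1430 with the values of the authors. The total of 1802 moved to 444 in a fit of the 9 arrays compared and to 1043 and 1084 without 15 h low-dose replicate 1 and replicate 2. In the fit of 9 arrays only Vim of the 6 raised astrocyte markers kept its call (Gfap adjusted p = 0.0856, Aqp4 0.201, Clu 0.0912, Gja1 0.147, Slc1a3 0.161). With median centring Aqp4 (0.0715), Gja1 (0.169) and Slc1a3 (0.187) did not pass, nor did the latter 2 in the authors' table (0.0718 and 0.0859). Pop4 did not pass without 15 h low-dose replicate 3 (-0.48, adjusted p = 0.50), without control 1, 3, 5 or 6 (adjusted p = 0.0597 to 0.0754), in the fit of 9 arrays (0.223), or with array weights (0.14), a separate variance for control arrays (0.0992), a variance trend (0.0704) or no filter on dim probes (0.0803).

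At 0.1 µM for 24 h 244 genes differed from the controls, against 2204 with median centring and 1934 in the authors' table. Met, a growth factor receptor gene (1.36 ± 0.30, adjusted p = 0.0265), the peptide gene Grp (1.32 ± 0.29), Sirpa (1.15 ± 0.27), Hspb8 (1.04 ± 0.23, adjusted p = 0.0263) and the immediate early gene Egr1 (0.98 ± 0.17, adjusted p = 0.00971) rose. Npy (-1.35 ± 0.25, adjusted p = 0.0115), the granin gene Scg2 (-1.32 ± 0.33), Cyp26b1 (-1.28 ± 0.28), Pdrg1 (-1.19 ± 0.27) and Dcn (-1.17 ± 0.25) fell. Npy, Cyp26b1 and Dcn were also among the largest falls at 15 h. Both times were compared with the same controls, so this repeat is not independent. Hspb1 was detected on no low-dose array at 24 h, and Ddit3 (-0.57 ± 0.18, adjusted p = 0.0849) did not pass the test. Among the 32 proteasome genes only Psmb3 (0.44 ± 0.076) and Psmc3 (0.34 ± 0.072) rose (5 adjusted over the list alone). The proteasome list median of 0.074 turned to -0.15 with median centring and -0.091 in the authors' table (camera adjusted p = 0.00486, adjusted p = 0.112 with an estimated correlation). Of 29 ATF4 targets 2 fell (14 adjusted over the list alone; median -0.39, camera adjusted p = 1.59e-06, adjusted p = 0.242 with an estimated correlation), with within-slide medians of -0.37, 0.0081 and -0.73. Of 27 NRF2 targets 4 rose (also 4 adjusted over the list alone). Their median of 0.17 was -0.016 with median centring (camera adjusted p = 0.00486, adjusted p = 0.349 with an estimated correlation, and 0.0622 without control 3).

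The 24 h low-dose total of 244 genes (76 higher and 168 lower, 5 and 9 by at least 2-fold, 98% in the same direction on every slide) rested on single arrays and on the scaling. It moved to 539 with slide as a block, 151 with cyclic loess, 403 with array weights, 391 with a separate variance for control arrays, and 84 without controls 5 and 6. In a fit of the 9 arrays compared limma called 0 genes, with 1149 at unadjusted p < 0.05. The split was 71 higher and 2133 lower with median centring, which moved the median of all genes from -0.029 to -0.205, and 80 and 1854 in the authors' table (to -0.13). Leaving out an array gave 109, 467, 435, 963 and 86 genes without control 1, 2, 3, 4 and 6. It gave 6, 3 and 58 without low-dose replicate 1, 2 and 3. Every named gene of that comparison lost its call in the fit of 9 arrays (adjusted p = 0.388 to 0.415), without low-dose replicate 1 (adjusted p = 0.0773 to 0.174 for the 10 largest changes) and without replicate 2 (0.0644 to 0.133). Replicate 3 ended the calls of Grp, Sirpa, Hspb8, Scg2, Cyp26b1, Pdrg1 and Dcn (0.051 to 0.104), and control 6 those of Met, Grp, Hspb8, Scg2, Cyp26b1, Pdrg1 and Dcn (0.0503 to 0.0593). Control 1 ended those of Sirpa, Scg2 and Pdrg1 (0.0536 to 0.0596) and control 5 that of Scg2 (0.0634). Without controls 5 and 6 Met, Grp, Hspb8, Cyp26b1, Pdrg1 and Dcn did not pass (0.0687 to 0.0916), Scg2 was at 0.0568 with cyclic loess, and Scg2 and Sirpa were at 0.0672 and 0.0501 with no filter on dim probes. Psmb3 and Psmc3 were at 0.209 and 0.77 with median centring and at 0.058 and 0.0773 without replicate 1.

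Compared directly at 0.1 µM, 521 of the 929 genes that were higher at 15 h were lower at 24 h than at 15 h, and 274 of the 873 lower ones were higher. Both comparisons use the same 15 h arrays, so some return arises even without a change. How much was not computed. Against the controls 29 and 55 of these genes were still called in their direction at 24 h. From 15 to 24 h 21 of 32 proteasome genes fell (25 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 1.73e-18). The within-slide medians were -0.51, -0.50 and -0.53. In a fit of the low-dose arrays alone camera with an estimated correlation gave an adjusted p of only 0.0266. Of 27 NRF2 targets 18 fell (23 adjusted over the list alone; median -0.59, camera adjusted p = 2.53e-14). Of 25 heat shock genes 6 fell (7 adjusted over the list alone; median -0.099, camera adjusted p = 0.0141). Of 25 synaptic vesicle genes 8 rose (11 adjusted over the list alone; median 0.23, camera adjusted p = 9.19e-07). Of 19 cholesterol synthesis genes 7 rose and 1 fell (11 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 1.75e-06, adjusted p = 0.169 with an estimated correlation). limma called 496 genes higher and 780 lower (10 and 115 by at least 2-fold), with splits of 154 and 669 with median centring and 214 and 825 in the authors' table. The total of 1276 moved to 2774 with array weights, 2392 with a separate variance for control arrays. It was 819 and 832 without 15 h low-dose replicate 2 and replicate 3, and 777 and 846 without 24 h low-dose replicate 1 and replicate 2.

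**Figure D3:**
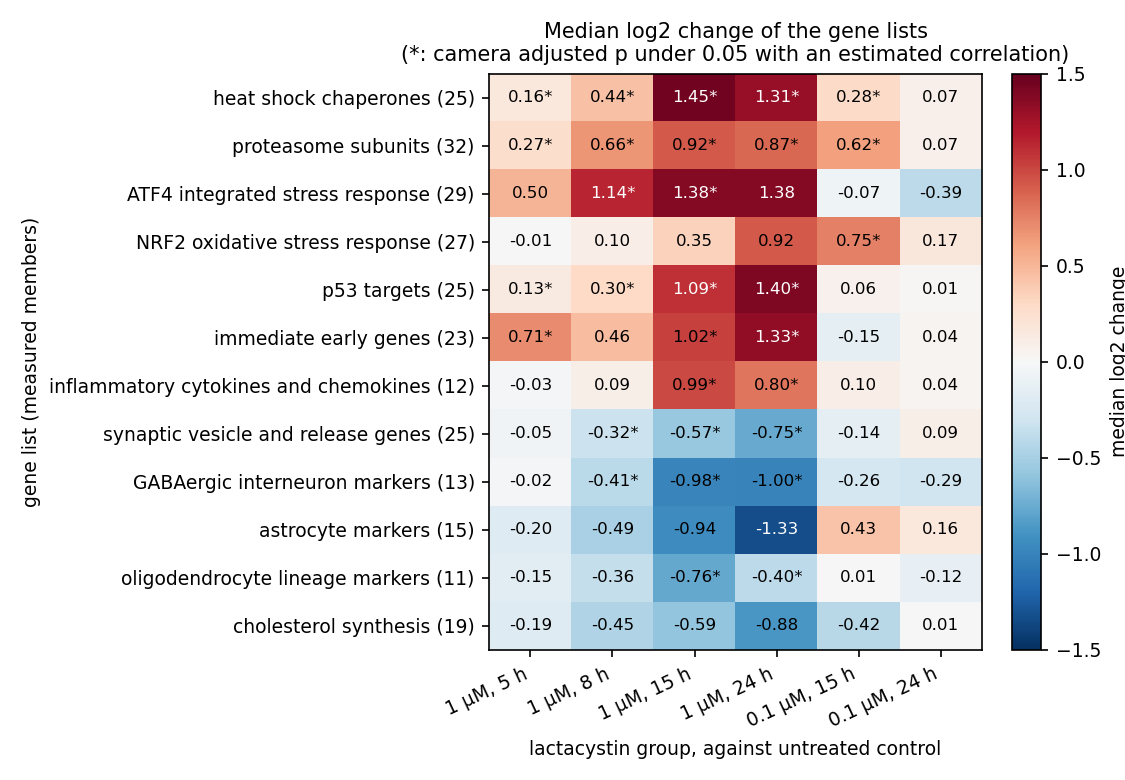
Median log2 change of 12 gene lists against the 6 controls, by dose and time, with an asterisk where camera passed with an estimated correlation. Proteasome subunits stood at 0.62 at 15 h of 0.1 µM and at 0.074 at 24 h, where median centring (-0.15) and the authors' table (-0.091) turned the sign, and at 0.92 and 0.87 at 1 µM.

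With 15 h at both doses compared directly, heat shock, ATF4 and p53 genes were higher at 1 µM and astrocyte markers lower. Hspb1 was higher by 5.89 ± 0.18 (adjusted p = 5.28e-16), Trib3 by 4.28 ± 0.42, Tnfrsf12a by 4.19 ± 0.18, Gdf15 at least 24.3-fold and Atf3 at least 18.5-fold. Lower were 0610041G09Rik (-4.45 ± 0.41), Sox10 (-4.19 ± 0.10, adjusted p = 5.99e-18, detected on 2 of 3 high-dose arrays), Prelp (-4.16 ± 0.24, detected on 1 of 3), Pdgfra (-3.78 ± 0.14) and Thrsp (at least 11.4-fold). Of these, Thrsp (1.33 at 0.1 µM and -2.91 at 1 µM), 0610041G09Rik (1.85 and -2.60) and Prelp (0.92 and -3.24) had moved in opposite directions against the controls. In the fit of the 9 arrays compared none of these low-dose rises passed (adjusted p = 0.0678, 0.0547 and 0.0856). Of 25 heat shock genes 17 were higher and 1 lower (also 17 and 1 adjusted over the list alone; median 0.79, camera adjusted p = 1.97e-06). Of 29 ATF4 targets 27 were higher (also 27 adjusted over the list alone; median 1.57, camera adjusted p = 9.37e-15, adjusted p = 0.0542 with an estimated correlation). Of 25 p53 targets 19 were higher and 2 lower (also 19 and 2 adjusted over the list alone; median 1.03, camera adjusted p = 1.20e-06). Of 32 proteasome subunits 14 were higher and 2 lower (also 14 and 2 adjusted over the list alone), but the list did not pass (median 0.26, camera adjusted p = 0.0742), and Psmb5 was at -0.090 ± 0.092 (adjusted p = 0.436). NRF2 targets were split, 8 higher and 13 lower of 27 (also 8 and 13 adjusted over the list alone; median -0.32, camera adjusted p = 0.352). Hmox1 (3.02 ± 0.24) and Osgin1 (2.84 ± 0.20) were higher, and the glutathione transferase genes Gstm1 (-2.84 ± 0.15) and Gsta4 (-1.43 ± 0.24) lower. Of 15 astrocyte markers 13 were lower (also 13 adjusted over the list alone), with Aqp4 at -3.69 ± 0.28 and Gfap at -2.51 ± 0.40 (median -1.21, camera adjusted p = 5.57e-06, adjusted p = 0.0548 with an estimated correlation). limma called 2832 genes higher and 2763 lower (618 and 785 by at least 2-fold), 99.2% of them in the same direction on every slide.

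At 24 h the doses differed in 18 of 31 gene lists by camera (6 with an estimated correlation). Hspb1 was higher at least 167-fold at 1 µM (adjusted p = 8.85e-18), Tnfrsf12a by 5.96 ± 0.18 (adjusted p = 1.00e-16), Trib3 by 5.32 ± 0.42 (detected on 2 of 3 low-dose arrays), Gdf15 at least 27.7-fold and Atf3 at least 16.4-fold. Aqp4 was lower by 4.37 ± 0.28 (adjusted p = 2.73e-11), Sox10 by 3.80 ± 0.10, Cmtm5 by 3.74 ± 0.18 (detected on 2 of 3 high-dose arrays), Cldn10 by 3.58 ± 0.20 and Thrsp at least 8.22-fold. Proteasome genes were higher in 26 of 32 cases and lower in 2 (28 and 2 adjusted over the list alone; median 0.71, camera adjusted p = 8.73e-08). Of 27 NRF2 targets 16 were higher and 2 lower (also 16 and 2 adjusted over the list alone; median 0.61, camera adjusted p = 2.42e-04, adjusted p = 0.222 with an estimated correlation). Of 25 p53 targets 19 were higher and 2 lower (also 19 and 2 adjusted over the list alone; median 1.32, camera adjusted p = 9.39e-09). Gadd45a was at 3.61 ± 0.12 and Mdm2 at 2.64 ± 0.096. Of 25 synaptic vesicle genes 21 were lower (also 21 adjusted over the list alone), with Slc17a7 at -2.27 ± 0.23 (median -0.89, camera adjusted p = 4.31e-09). Within the slides those medians were -0.95, -0.88 and -0.96. limma called 2905 genes higher and 2944 lower (824 and 816 by at least 2-fold), 99.4% of them in the same direction on every slide.

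Of the 244 genes called at 24 h of 0.1 µM 176 were also called at 1 µM, 90 in the same direction and 86 in opposite directions. Against the same 6 controls 21 genes were higher and 69 lower at both doses (20.3 and 51.6 for independent lists, 0 and 0 in 100 simulations of unchanged groups), among them Hspb8 as a gene higher at both. A further 35 were higher at the low and lower at the high dose and 51 the reverse (23.4 and 44.9 for independent lists). With the controls divided between the doses these 4 counts were 15, 29, 20 and 37, or 79, 171, 225 and 223. The covariance of the changes was -0.011 (0.0071 when simulated without effect), and -0.014 and -0.030 with the controls divided between the doses. At 15 h 392 genes were higher and 395 lower at both doses (253 and 242 for independent lists, 0 and 0 simulated), with 228 and 186 in opposite directions (258 and 237.5 for independent lists) and a covariance of 0.027. With divided controls these 4 counts were 282, 226, 91 and 81, or 408, 416, 470 and 358. The covariance then was 0.038 and -0.0051, so its sign depended on which controls served which dose. Groups simulated without effect leave hardly any genes to call, so their counts of 0 do not bear on sharing between the doses. The 90 genes shared in direction at 24 h became 854 with median centring, 766 in the authors' table and 172 with slide as a block. There were 325 without control 4 and 37 without controls 5 and 6. The number fell to 0 in fits of only the groups compared, and to 3 and 2 without 24 h low-dose replicate 1 and replicate 2.

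**Figure D4:**
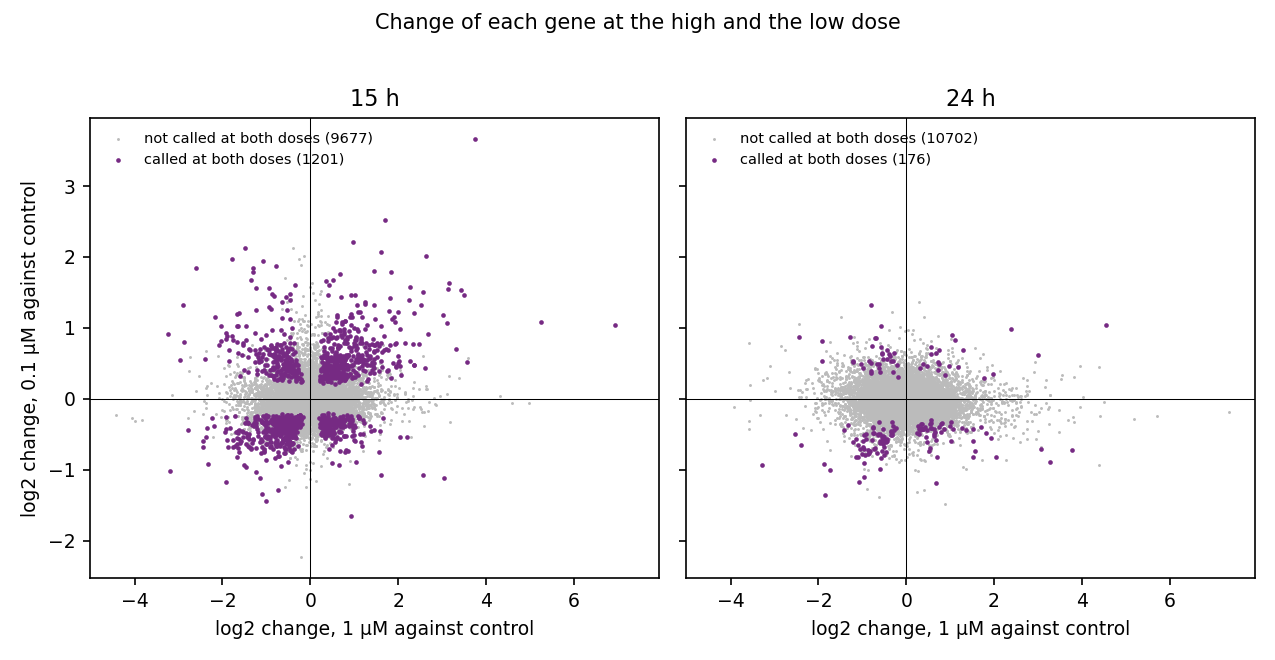
Log2 change against control at 1 µM (horizontal) and 0.1 µM (vertical) for 10878 genes at 15 and 24 h, with genes called at both doses coloured. At 15 h 1201 genes were called at both doses and at 24 h 176.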

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

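The tests on the spread of the controls, on glial cell loss and on the fading of the low-dose response and the regroupings within slides were chosen after the result was seen, and the scaling test of the glial lists and the other regroupings before.

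Of 110 items tested (108 genes and 2 array measures) 4 genes stood out, fewer than the 1 in 20 that chance alone marks. Fosb on control 5 (log2 intensity 7.186), G6pdx on control 6 (7.061), Hspb8 on control 2 (8.008) and B2m on control 2 (9.586) lay apart from the other 5 control arrays by more than Dixon's limit. That test takes only the most extreme array, so 2 arrays that lie apart together hide each other. In Trib3 controls 5 and 6 (7.345 and 7.291) did so against 4.976 to 6.248 in the others. The low count therefore does not show that the controls hold no outlying arrays. The interaction test asked whether the difference of 1 µM from 0.1 µM changed from 15 to 24 h, and limma called 1829 genes. The median interaction was 0.493 in proteasome subunits (18 of 32 genes called higher, 21 adjusted over the list alone), 0.342 in p53 targets (7 of 25, 8 adjusted over the list alone) and -0.507 in synaptic vesicle genes (14 of 25 lower, 18 adjusted over the list alone). It was 0.922 in NRF2 targets (17 of 27 higher, 21 adjusted over the list alone), whose median difference between the doses was -0.32 at 15 h and 0.61 at 24 h. In neural progenitor markers it was 0.586 (6 of 13 higher, 9 adjusted over the list alone), with a median difference of -0.86 at 15 h and -0.15 at 24 h. Among the 49 kept probes with no gene name, which no list could use, 14 were higher and 9 lower at 24 h of 1 µM. Of all genes tested 57.5% were called in that comparison.

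Control arrays differed more from each other than treated triplicates did, and the test on slide was revised more than once after its values were seen. A slide effect shared by all arrays is not the whole cause: 11 of 12 control pairs on different slides differed more than the most different treated pair (0.31 log2 units), and treated pairs all lie on different slides. A difference between slides among the controls alone stays open, since 1 of the 3 control pairs on the same slide (0.287, 0.306 and 0.352) differed more than that. The widest differences involved controls 5 and 6, both on slide 3, which differed from controls 1 to 4 by 0.345 to 0.544. Controls on slides 1 and 2 differed across the slides by 0.29 to 0.399. On the second principal component controls 5 and 6 lay at 18.4 and 16.2, near the 5 h arrays (18.7 to 20). The other controls lay at -11.2 to 2.1 there. On the first component controls 5 and 6 lay between the other controls and the 5 h arrays. Array brightness does not account for the wider spread of the controls, since 9 of 12 control pairs with median signals as close as those of treated pairs still differed more. The labels give no collection time for controls, so cultures of unequal age among them might be behind the spread, which no test here could address.

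Glial marker lists were lower at 1 µM for 15 h, though the astrocyte list did not pass camera with an estimated correlation. Scaling does not account for this: the highest median of the astrocyte and oligodendrocyte lists over 4 scalings was -0.603. Loss of glial cells would lower all their markers alike, and 7 of 26 measured members were not lower: Vim was higher, and the others, among them Gja1, Clu, Slc1a3, Cspg4 and Mbp, did not pass the test. Since some of these genes are also expressed by other cells, that count does not separate fewer glial cells from lower transcription in them, and both could be involved. Loss of neurons was not tested for the synaptic vesicle and GABAergic lists, which also fell.

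The proteasome list, raised at 15 h of 0.1 µM, had a lower median at 24 h. Compared directly, 15 and 24 h differed by a median of -0.518. No control array enters that value, so the spread of the controls cannot have set it. A fit of the 6 low-dose arrays alone could change only its test (camera adjusted p = 0.0266 with an estimated correlation). Slide is not the cause, since the highest of the 3 within-slide medians was -0.502. No slide position (0) held arrays of both times, so position and time cannot be told apart. A response that fades as the inhibitor is used up or removed would be in line with these values, and inhibitor activity was not measured.

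Regrouping the same arrays tested whether chance could give the counts. For 1 µM against control at 8, 15 and 24 h only the real grouping, 1 of 84, reached its count. These counts were 4347, 5980 and 6251, against 2179, 1967 and 2060 at the highest other. The same held, by a narrower margin, for 0.1 µM at 15 h (1802, highest other 1650). Random grouping is thus an unlikely source of these counts. At 5 h of 1 µM 3 of 84 groupings reached the real count of 1119, a share under 0.05, but the highest other gave 1646. Chance is not excluded there. For 0.1 µM at 24 h it cannot be excluded by these regroupings: 6 of 84 gave as many as the 244 genes, the highest of them 1913. That grouping set controls 1, 5 and 6 apart and so points to structure among the control arrays. The grouping with 1646 genes at 5 h likewise set controls 2, 3 and 4 apart from the other controls and the 5 h arrays. With slide as a block and arrays regrouped only within slides, the real grouping alone, 1 of 27, reached its count in each comparison with the controls. That is the smallest share that 27 regroupings can give, with no adjustment over the comparisons. At 1 µM the real counts were 1525 (5 h, highest other 413), 4924 (8 h, 753), 6406 (15 h, 463) and 6669 (24 h, 575). At 0.1 µM they were 2254 (15 h, 1103) and 539 (24 h, 387). For 0.1 µM at 24 h chance is still not excluded. There 6 of 84 regroupings reached the 244 genes, and the fit of only the groups compared called 0. For 3 against 3 arrays 10 groupings are too few for a share under 0.05, with 5595, 5849, 5172 and 1276 genes against 0 at the highest other. For the interaction 13 of 100 regroupings reached 1829 and the highest gave 6834, because exchanged labels carry the dose effect itself, so chance cannot be excluded by this test.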

How the results depend on the processing

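The slide of the labels as a block, the fit without controls 5 and 6 and the separate variance for control arrays were chosen after the result was seen. Median centring gave 673 genes at 5 h of 1 µM, 2204 at 24 h of 0.1 µM, 823 for 24 h against 15 h of 0.1 µM, 1086 for the interaction and 854 shared between the doses at 24 h. The authors' table gave 1934 at 24 h of 0.1 µM and 766 shared, and cyclic loess 151 at 24 h of 0.1 µM. With only the groups compared the counts were 131 (5 h of 1 µM), 444 (0.1 µM at 15 h), 0 (0.1 µM at 24 h) and 0 shared. Array weights gave 2395 at 5 h of 1 µM, 403 at 24 h of 0.1 µM, 2774 for 24 h against 15 h, 3539 for the interaction and 142 shared, and a separate variance for control arrays 391, 2392 and 2952 for the latter comparisons. Residuals of same-slide treated arrays correlated at 0.335 and 0.366 on slides 2 and 3 but at 0.0404 on slide 1. Slide thus tied the arrays on at least 2 of 3 slides. Residuals were taken from group means of 3 treated arrays, so a slide lying between the other 2 shows little correlation. The value on slide 1 therefore does not show that it was free of a slide effect. On the third principal component slide 1 lay between slides 3 and 2 in every treated group. At 15 h of 1 µM the values were -6.9, 3.56 and 10.9 on slides 3, 1 and 2. It was left out of the main model because the labels and series text name no block, so the main p-values ignore this tie. With slide as a replicate block the fit gave 539 genes at 24 h of 0.1 µM and 172 shared, and with the slide of the labels as a block 450 and 154. Without controls 5 and 6 there were 2549 genes at 5 h of 1 µM, 84 at 24 h of 0.1 µM and 37 shared. Leaving out 1 array gave 453 to 1683 genes at 5 h, 3499 to 4772 at 8 h, 5298 to 6103 at 15 h and 5576 to 6421 at 24 h of 1 µM, 1043 to 2200 and 3 to 963 at 15 and 24 h of 0.1 µM, 5029 to 5153 and 5313 to 5429 between the doses, 4573 to 4703 for 24 h against 5 h, 777 to 905 for 24 h against 15 h, 1435 to 1590 for the interaction and 2 to 325 shared. Of 162 list tests called by camera 67 stayed with an estimated correlation. At 24 h of 0.1 µM list medians turned sign: proteasome subunits to -0.154 with median centring and -0.0905 in the authors' table, NRF2 targets to -0.0163 with median centring, synaptic vesicle genes to -0.142 and -0.0752, and astrocyte markers to -0.109 and -0.0458. Scg2 at 15 h of 0.1 µM, not called (-0.0013), stood at 0.55 without controls 5 and 6.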

Other observations

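The lists on progenitors and on the immunoproteasome were singled out after the result was seen. The Notch targets Hes1 (1.33 ± 0.15, adjusted p = 3.70e-06) and Hes5 (0.93 ± 0.14), both on the list of progenitor markers, rose at 5 h of 1 µM. By 15 h Hes5 had fallen to -3.99 ± 0.14, while the filament gene Nes rose by 1.44 ± 0.14 at 15 h and 1.55 ± 0.14 at 24 h. Of 13 neural progenitor markers 9 fell and 2 rose at 15 h of 1 µM (also 9 and 2 adjusted over the list alone; median -0.48, camera adjusted p = 0.0127), and the within-slide medians were -0.66, -0.38 and -0.51. At 24 h 5 fell and 2 rose (also 5 and 2 adjusted over the list alone; median -0.21, camera adjusted p = 0.562). With 15 h at both doses compared, 9 were lower and 1 higher at 1 µM (also 9 and 1 adjusted over the list alone; median -0.86, camera adjusted p = 6.55e-04).

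The immunoproteasome list also holds genes of antigen presentation. At 0.1 µM for 15 h the peptide transporter gene Tap2 rose by 1.37 ± 0.23 (adjusted p = 3.47e-04) and B2m by 0.86 ± 0.14, and of 8 listed genes 3 rose (also 3 adjusted over the list alone; median 0.33, camera adjusted p = 0.00474, adjusted p = 0.152 with an estimated correlation). At 1 µM the proteasome activator genes Psme1 (-1.32 ± 0.12, adjusted p = 4.40e-09) and Psme2 (-1.05 ± 0.096) fell at 15 h. The list did not pass there (1 higher and 3 lower, 1 and 5 adjusted over the list alone; median -0.53, camera adjusted p = 0.137). At 8 h of 1 µM camera called the list lower. That call ended with cyclic loess (median -0.349, camera adjusted p = 0.051) and in the fit of only the groups compared (median -0.356, camera adjusted p = 0.0593). Between the doses at 15 h 6 of 8 were lower at 1 µM (also 6 adjusted over the list alone), Tap2 by 1.89 ± 0.27 (median -1.05, camera adjusted p = 0.00452, adjusted p = 0.135 with an estimated correlation).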
